A study of Mus musculus with 16 samples.

How the data were processed

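RNA was measured in Sertoli cells from the testes of male mice that carry a fluorescent protein cassette in the 3' untranslated region of Sox9, at 5, 10, 18, 25 and 35 days after birth. Per the labels' protocols, RNA that passed an integrity check was pooled into triplicates for each age, selected for poly(A), fragmented and sequenced from single ends. The labels list 16 samples. P25 replicate 2 was run as a pair of samples, 1 of them paired-end, whose processed data were combined per the labels, and it was counted as 1 library. This gave 15 libraries, 3 per age, grouped by the age in their titles.

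Per the submitters' processing notes, TopHat 1.4.1, Cufflinks 1.2.0, Cuffdiff and bedtools 2.12.0 were used with the mouse genome build mm9. The role, order and settings of these tools are not given in the sources used here. The authors deposited a table of log2 FPKM, a read count scaled to transcript length and library size, for each transfrag (assembled transcript fragment) in each library. The deposited log2 values were quantile-normalized across the libraries by the authors, per the name of the table and its values, and their floor shows that 0.05 had been added before the logarithm. The authors also deposited the assembly itself, with exons, gene symbols and class codes that relate each transfrag to the annotation, and read coverage for each library. The deposited coverage signal is the number of aligned reads over each interval, not scaled to depth, per its values. Reads standing alone covered 100 bases, more than the read length in the labels. 0 columns of values were left without a sample.

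These steps shape the measurements. Quantile normalization can remove a shift most transcripts share, but libraries still differed (26.8 to 47.1% of transfrags at the floor). FPKM divides by length, so that a few reads on a short transfrag give a high value. Of the transfrags, 8281 were 200 bases or shorter, and they held 43.5 to 78.3% of the summed FPKM of a library. Of 544 transfrags above 2000 FPKM in any library, 518 were that short. Coverage over exons was therefore computed as a readout that does not use these values. Reads of a gene and of an overlapping or antisense neighbour, or of a near-identical copy, could not be told apart.

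The added 0.05 was taken off, and values at the floor were set to 0. FPKM was summed over all transfrags that share a gene symbol, intronic and antisense included (107422 transfrags, 25578 gene names). Genes with at least 1 FPKM in at least 3 libraries were kept, which left 20647. Testing used log2(FPKM + 1), and log2 changes are on that scale. As another readout, the mean coverage of each gene's exons was divided by the total covered bases of its library, on the same scale and with the same minimum (15609 genes). Exons were those of the annotated transcripts where the assembly held any, and otherwise of transfrags that overlap exons on the same strand. Depth was taken as the total covered bases. FPKM holds no counts, so no counting interval is given, and precision comes from the spread between libraries.

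All libraries entered a single limma model (lmFit, eBayes with a mean-variance trend) with age as the factor and no covariate. The comparisons were P10 with P5, P18 with P10, P25 with P18, P35 with P25, and P35 with P5, besides an F test over the 5 ages. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. Assembled loci of which each transfrag lay between annotated genes were tested in the same way among themselves.

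The 25 gene lists were fixed before the data were examined, from textbook knowledge. They cover core, immature and mature Sertoli genes, junctions, basement membrane and matrix, growth factors, hormone receptors, retinoic acid, phagocytosis and lysosome, cell cycle, cell cycle inhibitors and imprinted genes. Further lists hold glycolysis and lactate, oxidative phosphorylation, cholesterol synthesis, lipid handling, and immediate-early and stress genes. Other cell types are covered by spermatogonial, spermatocyte, spermatid, Leydig, peritubular myoid, macrophage, endothelial and erythroid markers. Of 478 list entries 461 were matched to the assembly, 451 by symbol, 9 by an older name and 1 by an Ensembl identifier. Names came from the assembly and from a RefSeq table of a later mouse assembly, GRCm38.p6, used for names only. Rhox5 was not matched and has no value here. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 125 tests (25 lists in 5 comparisons), and again with an estimated correlation and with fry. Camera sets a list against the other genes, while fry asks whether the list's genes move, on balance, to the same side or, in its other form, change to either side.

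The genes to be named were set by rule before the data were examined. They include Sox9, Amh, Fshr, Wt1, Gata4, Gata1, Dmrt1, Clu, Trf, Rhox5, Cst12, Cldn11, Kitl, Gdnf and Inha, and 1 further gene that is not reported here. In each comparison they include the 5 largest rises and 5 largest falls past the threshold with a mean of at least 5 FPKM at the higher age and libraries fully apart. In each list and comparison they include up to 4 members with the largest change past the threshold, or else up to 2 with the highest FPKM. The rule also took the 5 intergenic loci with the smallest F test p. The same rule was applied to coverage after the data were examined. The examples printed were chosen from these genes after their values were seen, with preference for calls that held in both readouts and without each library. Of 289 gene comparisons so chosen 230 were called.

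Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, the highest transfrag per gene, renewed quantile normalization, rescaling to the median gene, other eBayes settings, only the libraries compared, a 2-fold minimum, the replicate number as a block, coverage, and leaving out each library. Before the fit was settled, 5 definitions of a gene's value were fitted and compared, and the definition written beforehand was kept. They were the sum over all transfrags, over exon-overlapping transfrags, over transfrags longer than 200 bases, over those that are both, and coverage. Each but the combination of both is reported. Alternatives added after seeing the data were exon-overlapping sense transfrags, leaving out transfrags of 200 bases or fewer, leaving out P5 library 3 and P10 library 1 together, coverage with a 2-fold minimum or rescaled, coverage of intergenic loci, and list tests on coverage, without both libraries and without each library, with either correlation.

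The procedure was tested on simulated data, with 200 genes changed in a simulated comparison of P35 with P25. In FPKM (20647 genes) it recovered 25% of the genes changed by 1 on the log2 scale and 62% of those changed by 2, with 7 false among 94 calls. In coverage (15609 genes) it recovered 86% and 99%, with 13 false among 198 calls. Regroupings of the libraries used seed 20 and at most 100 draws. Intervals of list medians are 95% bootstrap intervals over genes from 2000 resamples. End coverage was compared over the outer 500 bases of transcripts of at least 2000 bases with a summed end coverage of at least 1000.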

Results

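Poly(A)-selected RNA was sequenced from Sertoli cells of male Sox9-EGFP knock-in mice at 5 postnatal ages, P5, P10, P18, P25 and P35 (days after birth), with 3 libraries per age. Sertoli cells are the somatic cells of the seminiferous tubule that enclose and nourish germ cells, and Sox9 encodes a transcription factor of these cells. How the cells were isolated is not given in the sources used here. Each library was made from pooled RNA, and p-values measure the spread between pools, which may be technical and is estimated over all 5 ages together. The 15 libraries held 1.55 to 5.07 gigabases of aligned sequence (P25 library 2 and P5 library 3), with a median of 3.43. P25 library 2 was run in 2 parts, and whether its coverage holds both is not given in the sources used here, so that its depth is uncertain. Exons carried 78.1 to 83.0% of it. Expression is given as FPKM, mean ± SD of 3 libraries. A change is the difference in log2(FPKM + 1) ± SE, a scale that understates the change of low genes. Adjusted p-values come from limma over 20647 genes.

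Libraries of the same age had Pearson correlations of 0.813 to 0.930 across genes in FPKM and of 0.967 to 0.993 in read coverage over exons, where genes are not independent replicates. Between ages the range was 0.501 to 0.920 in FPKM and 0.652 to 0.982 in coverage. P5 library 3 and P10 library 1 stood apart in the FPKM table, with mean correlations of 0.815 and 0.826 with their replicates. In these libraries 78.3% and 71.6% of FPKM lay on transfrags (assembled transcript fragments) of 200 bases or fewer, against 43.5 to 60.9% in the others.

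**Figure D1:**
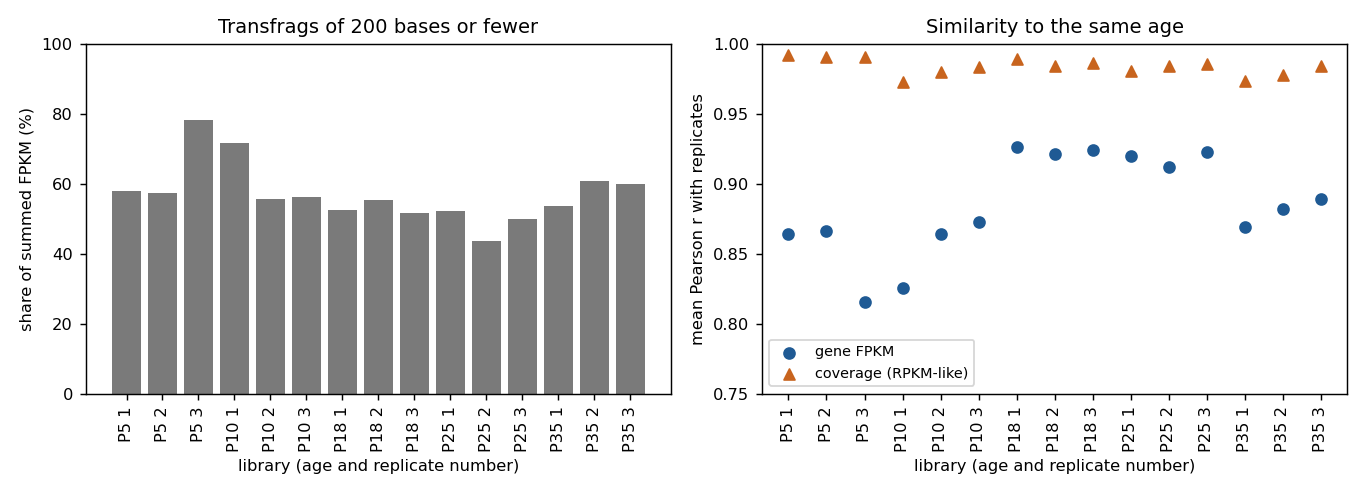
The left panel shows, for each of the 15 libraries, the percent of summed FPKM carried by transfrags of 200 bases or fewer, and the right panel each library's mean Pearson correlation across genes with its replicates, in FPKM and in read coverage, on an axis that starts at 0.75. P5 library 3 (78.3%) and P10 library 1 (71.6%) have the highest bars and the lowest FPKM correlations (0.815 and 0.826).

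The comparison of P10 with P5 spans the days when postnatal Sertoli cell division declines. Cell division genes were lower at P10. Of 28 measured cell cycle genes, 0 rose, 25 fell and 3 did not pass (0 rose and 26 fell adjusted over the list alone). The cell cycle list was lower as a group (camera adjusted p = 7.7e-24, adjusted p = 0.105 with an estimated correlation). Ube2c, an enzyme gene of mitotic exit, fell from 157 ± 70.8 to 12.7 ± 3.19 FPKM (log2 change -3.42 ± 0.34, adjusted p = 4.0e-05). Ccnd2, for a D-type cyclin, fell from 145 ± 53.5 to 34.3 ± 4.35 FPKM (log2 change -1.98 ± 0.27, adjusted p = 4.1e-04). Of 9 genes for cell cycle inhibitors, 3 rose, 0 fell and 6 did not pass (3 rose and 1 fell adjusted over the list alone). The inhibitor list did not pass as a group (camera adjusted p = 0.476), with a median of 0.22 and a mean of -0.29 on the log2 scale while the test pointed higher. Cdkn2a rose from 1.45 ± 1.08 to 17.1 ± 2.62 FPKM (log2 change 2.998 ± 0.36, adjusted p = 1.6e-04).

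Of 14 genes listed for immature Sertoli cells, 1 rose, 5 fell and 8 did not pass (1 rose and 5 fell adjusted over the list alone). The immature Sertoli list was lower as a group (camera adjusted p = 0.0119, adjusted p = 0.599 with an estimated correlation); without P5 replicate 1 the adjusted p was 0.0574. The keratin gene Krt8 fell from 27.6 ± 9.58 to 2.48 ± 2.05 FPKM (log2 change -3.14 ± 0.39, adjusted p = 1.8e-04). Ptgds, for prostaglandin D synthase, fell from 232 ± 145 to 21.7 ± 2.86 FPKM (log2 change -3.13 ± 0.64, adjusted p = 0.00534). Of 16 genes listed for mature Sertoli cells, 5 rose, 1 fell and 10 did not pass (5 rose and 1 fell adjusted over the list alone). The mature Sertoli list was higher as a group (camera adjusted p = 0.0274, adjusted p = 0.390 with an estimated correlation). Gata1, for a transcription factor of postnatal Sertoli cells, rose from 12.1 ± 2.21 to 87.4 ± 11.2 FPKM (log2 change 2.76 ± 0.19, adjusted p = 3.6e-06). Drd4, a dopamine receptor gene, rose from 3.55 ± 2.06 to 99.0 ± 25.03 FPKM (log2 change 4.52 ± 0.43, adjusted p = 2.8e-05). Spinlw1, which encodes the protease inhibitor Eppin, rose from 4.97 ± 0.804 to 91.1 ± 16.01 FPKM (log2 change 3.94 ± 0.28, adjusted p = 3.6e-06). Cldn11, for a claudin of the blood-testis barrier, rose from 168 ± 74.4 to 1098 ± 639.6 FPKM (log2 change 2.54 ± 0.61, adjusted p = 0.0127), a call that ended without P10 replicate 2 or P10 replicate 3.

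Of 19 growth factor genes, 0 rose, 4 fell and 15 did not pass (0 rose and 4 fell adjusted over the list alone). The growth factor list was lower as a group (camera adjusted p = 0.0143, adjusted p = 0.485 with an estimated correlation); without P5 replicate 2 the adjusted p was 0.0723. Gdnf, for the factor that maintains spermatogonial stem cells, fell from 56.7 ± 11.4 to 13.6 ± 2.40 FPKM (log2 change -1.98 ± 0.21, adjusted p = 5.9e-05). Of 24 basement membrane and matrix genes, 2 rose, 6 fell and 16 did not pass (3 rose and 7 fell adjusted over the list alone). The basement membrane list did not pass as a group (camera adjusted p = 0.284). The protease gene Mmp2 fell from 170.4 ± 97.8 to 13.9 ± 10.1 FPKM (log2 change -3.58 ± 0.51, adjusted p = 5.4e-04). Timp2, for a metalloproteinase inhibitor, rose from 5.01 ± 0.559 to 63.2 ± 17.8 FPKM (log2 change 3.38 ± 0.27, adjusted p = 7.2e-06). Of 16 imprinted genes, 0 rose, 8 fell and 8 did not pass (0 rose and 11 fell adjusted over the list alone). The imprinted list was lower as a group (camera adjusted p = 3.9e-06, adjusted p = 0.187 with an estimated correlation). The non-coding RNA gene H19 fell from 64.0 ± 20.2 to 13.4 ± 5.09 FPKM (log2 change -2.18 ± 0.26, adjusted p = 1.4e-04). Of 20 retinoic acid genes, 6 rose, 3 fell and 11 did not pass (6 rose and 3 fell adjusted over the list alone). The retinoic acid list did not pass as a group (camera adjusted p = 0.0975, adjusted p = 0.624 with an estimated correlation), but passed without both P5 library 3 and P10 library 1 (adjusted p = 0.0476, adjusted p = 0.465 with an estimated correlation), and not in coverage (adjusted p = 0.117). Crabp1, for a retinoic acid binding protein, rose from 1.63 ± 0.387 to 25.7 ± 7.43 FPKM (log2 change 3.32 ± 0.24, adjusted p = 3.6e-06).

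Of 18 spermatogonial genes, 14 rose, 0 fell and 4 did not pass (16 rose and 0 fell adjusted over the list alone). The spermatogonial list was higher as a group (camera adjusted p = 4.1e-11, adjusted p = 0.172 with an estimated correlation). Dazl, a germ cell gene, rose from 7.83 ± 1.91 to 98.6 ± 44.2 FPKM (log2 change 3.40 ± 0.34, adjusted p = 3.6e-05). Of 22 spermatocyte genes, 12 rose, 0 fell and 10 did not pass (14 rose and 0 fell adjusted over the list alone). The spermatocyte list was higher as a group (camera adjusted p = 1.5e-07, adjusted p = 0.239 with an estimated correlation). The meiotic cohesin gene Rec8 rose from 3.09 ± 0.786 to 65.5 ± 20.97 FPKM (log2 change 3.98 ± 0.23, adjusted p = 1.2e-06). Of 19 immediate-early and stress genes, 0 rose, 8 fell and 11 did not pass (0 rose and 10 fell adjusted over the list alone). The immediate-early list was lower as a group (camera adjusted p = 9.3e-05, adjusted p = 0.403 with an estimated correlation). Nr4a1 fell from 507 ± 378 to 25.1 ± 11.3 FPKM (log2 change -4.08 ± 0.57, adjusted p = 4.3e-04). The Leydig, endothelial, myoid, macrophage and spermatid lists did not pass as groups, with camera adjusted p = 0.404, 0.147, 0.267, 0.211 and 0.741. The macrophage list passed in coverage, higher (adjusted p = 0.0436, adjusted p = 0.326 with an estimated correlation), and the endothelial list passed without P10 replicate 1 but not in coverage (adjusted p = 0.105), with an adjusted p of at least 0.538 with an estimated correlation without any 1 library. Cd74, an antigen presentation gene of the macrophage list, rose from 0.720 ± 0.259 to 24.997 ± 6.76 FPKM (log2 change 3.89 ± 0.28, adjusted p = 4.1e-06). At P5, FPKM was already at least 1 for 12 of the 18 spermatogonial, 11 of the 22 spermatocyte and 4 of the 25 spermatid genes. The same held for 10 of the 10 Leydig, 8 of the 10 myoid, 6 of the 12 macrophage and 9 of the 11 endothelial genes, and 0 of the genes in these lists stood in another list.

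In all, 3454 genes differed between P10 and P5, 1979 higher and 1475 lower (57.3% higher). With gene sums rescaled to the median gene 1746 were higher and 2075 lower (45.7% higher), and in coverage rescaled likewise 2327 and 2719 (46.1% higher). Without P5 replicate 3, 1589 were higher and 1851 lower. A mean of at least 5 FPKM called 2120 genes (1288 higher), only the libraries of the 2 ages 1602 (976 higher), and coverage with a 2-fold minimum 1421 (680 higher). The median gene changed by 0.05 on the log2 scale as deposited and by -0.07 after rescaling. Amh, the anti-Müllerian hormone gene, was at 745 ± 554 (105 in P5 library 3) and 245 ± 48.8 FPKM. It did not pass (log2 change -1.03 ± 0.82, adjusted p = 0.454), but fell in coverage (log2 change -1.78 ± 0.35, adjusted p = 0.00115). Gata4 was at 277 ± 115 and 127 ± 12.4 FPKM (log2 change -1.02 ± 0.34, adjusted p = 0.0624) and fell in coverage (log2 change -1.16 ± 0.15, adjusted p = 3.1e-05). Fshr, the gene of the receptor for follicle-stimulating hormone, was at 695 ± 703 and 613 ± 543 FPKM (log2 change 0.17 ± 1.60, adjusted p = 1.0) and fell in coverage (log2 change -0.61 ± 0.11, adjusted p = 6.7e-04). Sox9 was at 704 ± 363 and 1052 ± 352 FPKM (log2 change 0.69 ± 0.52, adjusted p = 0.425). Wt1, for another Sertoli transcription factor, was at 99.8 ± 22.5 and 113 ± 10.1 FPKM (log2 change 0.20 ± 0.17, adjusted p = 0.473). Of the largest FPKM changes, those of Parp16, Fance and Cd180 rested on short transfrags, which carried 99.4%, 98.8% and 99.5% of their FPKM. Parp16 and Fance had log2 changes of 8.46 and 6.69 in FPKM but -0.02 and -0.06 in coverage. Among genes without short transfrags, Pcsk1n (6.06 ± 0.59, adjusted p = 3.2e-05) and Lpar3 (4.75 ± 0.23, adjusted p = 3.5e-07) rose, and Cbln1 (-4.83 ± 0.55, adjusted p = 1.0e-04) and Gdf15 (-4.34 ± 0.51, adjusted p = 1.2e-04) fell.

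Between P10 and P18, when the blood-testis barrier forms, Cldn3, for a claudin, rose from 0.544 ± 0.334 to 12.1 ± 4.32 FPKM (log2 change 3.04 ± 0.43, adjusted p = 4.0e-04). Shbg, which encodes androgen-binding protein, rose from 69.4 ± 10.4 to 199.7 ± 7.25 FPKM (log2 change 1.52 ± 0.22, adjusted p = 4.6e-04). Slc16a1, for a lactate transporter, rose from 27.2 ± 9.93 to 76.2 ± 7.67 FPKM (log2 change 1.52 ± 0.26, adjusted p = 0.00150).

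Of 22 phagocytosis and lysosome genes, 8 rose, 0 fell and 14 did not pass (9 rose and 0 fell adjusted over the list alone). The phagocytosis list was higher as a group (camera adjusted p = 1.7e-04, adjusted p = 0.487 with an estimated correlation). Pros1, whose product bridges dying cells to phagocyte receptors, rose from 6.25 ± 1.82 to 39.1 ± 4.49 FPKM (log2 change 2.50 ± 0.27, adjusted p = 6.8e-05). Mfge8, for another bridging protein, rose from 36.1 ± 1.63 to 164 ± 22.3 FPKM (log2 change 2.15 ± 0.40, adjusted p = 0.00255). Tfeb, for a regulator of lysosome genes, rose from 13.1 ± 1.34 to 37.7 ± 4.70 FPKM (log2 change 1.45 ± 0.18, adjusted p = 1.6e-04). Of 28 junction genes, 7 rose, 6 fell and 15 did not pass (10 rose and 6 fell adjusted over the list alone). The junction list did not pass as a group (camera adjusted p = 0.809), with a median log2 change of 0.24 (mean -0.15) while the test pointed higher. Espn, for an actin-bundling protein, rose from 121 ± 6.15 to 504 ± 215 FPKM (log2 change 1.96 ± 0.38, adjusted p = 0.00313). Of the mature Sertoli genes, 5 rose, 2 fell and 9 did not pass (7 rose and 2 fell adjusted over the list alone). The mature Sertoli list did not pass as a group (camera adjusted p = 0.0541, adjusted p = 0.403 with an estimated correlation), but passed with a pseudocount of 0.1 (adjusted p = 0.0431) and without P5 replicate 3, P10 replicate 3, P18 replicate 3, P25 replicate 3, P35 replicate 1 or P35 replicate 2 singly, and not in coverage (adjusted p = 0.0712). With an estimated correlation its lowest adjusted p without any 1 library was 0.330. Of 20 core Sertoli genes, 1 rose, 1 fell and 18 did not pass (1 rose and 0 fell adjusted over the list alone). In coverage 8 rose and 6 fell. The core list did not pass as a group (camera adjusted p = 0.512).

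Of the cell cycle genes at P18, 1 rose, 21 fell and 6 did not pass (1 rose and 24 fell adjusted over the list alone). The cell cycle list was lower as a group (camera adjusted p = 8.7e-15, adjusted p = 0.152 with an estimated correlation). Ccna2 fell from 16.3 ± 2.69 to 0.706 ± 0.245 FPKM (log2 change -3.34 ± 0.20, adjusted p = 1.4e-06). Ccnd2 fell from 34.3 ± 4.35 to 2.69 ± 0.756 FPKM (log2 change -3.27 ± 0.27, adjusted p = 1.0e-05). Cdkn1a, for the inhibitor p21, rose from 0.734 ± 0.187 to 9.95 ± 0.227 FPKM (log2 change 2.66 ± 0.26, adjusted p = 3.1e-05), and Cdkn2a fell from 17.1 ± 2.62 to 0.964 ± 0.443 FPKM (log2 change -3.22 ± 0.36, adjusted p = 8.4e-05). Of the growth factor genes at P18, 1 rose, 6 fell and 12 did not pass (1 rose and 6 fell adjusted over the list alone). The growth factor list was lower as a group (camera adjusted p = 0.00310, adjusted p = 0.403 with an estimated correlation). Wnt6 fell from 103 ± 17.7 to 5.65 ± 1.12 FPKM (log2 change -3.96 ± 0.43, adjusted p = 6.8e-05). Gdnf fell from 13.6 ± 2.40 to 7.85 ± 0.735 FPKM (log2 change -0.71 ± 0.21, adjusted p = 0.0314), a call that ended on leaving out P10 replicate 1 or 3 or any P18 replicate. Of the immature Sertoli genes at P18, 1 rose, 5 fell and 8 did not pass (1 rose and 6 fell adjusted over the list alone). The immature Sertoli list did not pass as a group (camera adjusted p = 0.128, adjusted p = 0.746 with an estimated correlation), but passed in coverage (lower, adjusted p = 0.00211, adjusted p = 0.389 with an estimated correlation). Of the imprinted genes at P18, 3 rose, 6 fell and 7 did not pass (4 rose and 7 fell adjusted over the list alone). The imprinted list did not pass as a group (camera adjusted p = 0.175). Dlk1 fell from 16.2 ± 0.606 to 0.0447 ± 0.0254 FPKM (log2 change -4.04 ± 0.18, adjusted p = 2.3e-07). Lpl, for lipoprotein lipase, fell from 22.5 ± 6.83 to 0.587 ± 0.424 FPKM (log2 change -3.88 ± 0.36, adjusted p = 2.0e-05). Crabp1 fell from 25.7 ± 7.43 to 1.23 ± 0.381 FPKM (log2 change -3.56 ± 0.24, adjusted p = 2.4e-06).

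Of the spermatogonial genes at P18, 1 rose, 15 fell and 2 did not pass (2 rose and 16 fell adjusted over the list alone). The spermatogonial list was lower as a group (camera adjusted p = 4.5e-09, adjusted p = 0.223 with an estimated correlation). Stra8, a gene of meiotic entry, fell from 27.5 ± 8.71 to 1.79 ± 1.14 FPKM (log2 change -3.38 ± 0.55, adjusted p = 0.00105). Of the spermatocyte genes at P18, 4 rose, 7 fell and 11 did not pass (4 rose and 7 fell adjusted over the list alone). The spermatocyte list did not pass as a group (camera adjusted p = 0.267). Ldhc, for a lactate dehydrogenase of meiotic and later germ cells, rose from 0.0674 ± 0.0908 to 11.6 ± 2.124 FPKM (log2 change 3.55 ± 0.22, adjusted p = 1.6e-06). Of the Leydig genes at P18, 0 rose, 4 fell and 6 did not pass (0 rose and 5 fell adjusted over the list alone). The Leydig list was lower as a group (camera adjusted p = 0.00273, adjusted p = 0.128 with an estimated correlation). Insl3, for a Leydig cell hormone, fell from 7.28 ± 1.12 to 0.384 ± 0.372 FPKM (log2 change -2.61 ± 0.29, adjusted p = 7.8e-05). Of the endothelial genes at P18, 0 rose, 7 fell and 4 did not pass (0 rose and 7 fell adjusted over the list alone). The endothelial list was lower as a group (camera adjusted p = 7.7e-04, adjusted p = 0.390 with an estimated correlation). Sox18 fell from 21.3 ± 3.66 to 2.23 ± 0.0345 FPKM (log2 change -2.78 ± 0.20, adjusted p = 3.6e-06). Of the myoid genes at P18, 0 rose, 6 fell and 4 did not pass (0 rose and 7 fell adjusted over the list alone). The myoid list was lower as a group (camera adjusted p = 0.00737, adjusted p = 0.223 with an estimated correlation), and in coverage adjusted p = 0.105. Of the macrophage genes at P18, 2 rose, 4 fell and 6 did not pass (2 rose and 5 fell adjusted over the list alone). The macrophage list did not pass as a group (camera adjusted p = 0.231).

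In all, 4124 genes differed between P18 and P10, 1834 higher and 2290 lower (44.5% higher). With gene sums quantile-normalized again the majority turned, with 2315 higher and 2046 lower (53.1% higher), and rescaled coverage gave 3007 and 3033 (49.8% higher). The majority also turned with a mean of at least 5 FPKM (1219 and 1039, 2258 in all) and with the highest transfrag per gene (1294 and 1271, 2565 in all). The 2-fold minimum left 1071 and 1706, and 558 and 1040 in coverage (1598 in all). Clu, among the most abundant Sertoli transcripts, did not pass in FPKM, at 3688 ± 2824 and 11308 ± 1633 FPKM (log2 change 2.29 ± 1.64, adjusted p = 0.385), but rose in coverage (log2 change 0.87 ± 0.19, adjusted p = 0.00207). The transferrin gene Trf was at 0.178 ± 0.164 and 0.806 ± 0.281 FPKM (log2 change 0.62 ± 0.28, adjusted p = 0.154) and also rose in coverage (log2 change 1.42 ± 0.26, adjusted p = 5.6e-04). Amh was at 245 ± 48.8 and 71.9 ± 49.1 FPKM (log2 change -2.10 ± 0.82, adjusted p = 0.0961) and fell in coverage (log2 change -1.76 ± 0.35, adjusted p = 0.00104). Fshr was at 613 ± 543 and 1399 ± 2260.2 FPKM (log2 change -0.45 ± 1.60, adjusted p = 0.918) and rose in coverage (log2 change 0.44 ± 0.11, adjusted p = 0.00571). Inha, for the inhibin alpha subunit, was at 399.7 ± 110.1 and 1012 ± 201 FPKM (log2 change 1.36 ± 0.61, adjusted p = 0.148). Short transfrags carried 98.7% of the FPKM of Rrp9 and 98.2% of that of the lipoprotein receptor gene Scarb1. Their log2 changes were 8.04 and 7.43 in FPKM but 0.06 and 0.64 in coverage. Among genes without short transfrags, Aqp8 (4.17 ± 0.38, adjusted p = 1.9e-05) and Emb (4.14 ± 0.28, adjusted p = 2.6e-06) rose, and Serpinf1 (-4.17 ± 0.31, adjusted p = 4.2e-06) and Mafa (-3.37 ± 0.39, adjusted p = 9.3e-05) fell.

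Between P18 and P25, when round spermatids appear in the mouse testis, spermatid genes rose. Of 25 measured spermatid genes, 17 rose, 0 fell and 8 did not pass (20 rose and 0 fell adjusted over the list alone). The spermatid list was higher as a group (camera adjusted p = 4.4e-29, adjusted p = 0.105 with an estimated correlation). The protamine gene Prm1 was listed at 0 in the 3 P18 libraries and at 8.17 ± 3.47 FPKM at P25 (adjusted p = 0.00153). Tnp1, for transition protein 1, was listed at 0 and at 4.78 ± 2.15 FPKM (adjusted p = 3.8e-04). Of the spermatocyte genes at P25, 6 rose, 0 fell and 16 did not pass (9 rose and 0 fell adjusted over the list alone). The spermatocyte list was higher as a group (camera adjusted p = 2.1e-11, adjusted p = 0.152 with an estimated correlation). Ldhc rose from 11.6 ± 2.124 to 60.04 ± 8.17 FPKM (log2 change 2.28 ± 0.22, adjusted p = 4.2e-04). Adam3, a sperm surface protein gene, rose from 0.733 ± 0.264 to 6.22 ± 1.399 FPKM (log2 change 2.05 ± 0.19, adjusted p = 3.6e-04). Ccna1, a germ cell cyclin gene, rose from 0.0729 ± 0.0263 to 2.63 ± 0.592 FPKM (log2 change 1.75 ± 0.20, adjusted p = 7.7e-04).

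No gene of the core, immature or mature Sertoli lists passed the limma test in FPKM between these ages (20, 14 and 16 measured). At an unadjusted p under 0.05, 0, 1 and 3 did, and in coverage 0, 1 (lower) and 0 passed the adjusted test. Their camera adjusted p-values were 0.788, 0.902 and 0.405. Gata1 was at 159 ± 7.90 and 167 ± 11.4 FPKM (log2 change 0.07 ± 0.19, adjusted p = 1.0). Cldn11 was at 2528 ± 203 and 2714 ± 144 FPKM (log2 change 0.10 ± 0.61, adjusted p = 1.0). Sox9 was at 859.97 ± 325 and 903 ± 24.9 FPKM (log2 change 0.15 ± 0.52, adjusted p = 1.0). Tgfbi, for a matrix protein, fell from 11.4 ± 1.28 to 2.23 ± 0.944 FPKM (log2 change -1.99 ± 0.32, adjusted p = 0.00516). Pam, for a peptide-amidating enzyme, fell from 22.3 ± 3.16 to 8.26 ± 1.502 FPKM (log2 change -1.33 ± 0.19, adjusted p = 0.00264). Of the basement membrane genes at P25, 0 rose, 0 fell and 24 did not pass (0 rose and 2 fell adjusted over the list alone). The basement membrane list was lower as a group (camera adjusted p = 0.00564, adjusted p = 0.403 with an estimated correlation), with a median log2 change of -0.21 and fry adjusted p = 0.144; 5 genes passed limma at an unadjusted p under 0.05, and in coverage 0 rose and 4 fell. Of the cell cycle genes at P25, 1 rose, 0 fell and 27 did not pass (3 rose and 0 fell adjusted over the list alone). The cell cycle list was higher as a group (camera adjusted p = 0.0119, adjusted p = 0.624 with an estimated correlation), with fry adjusted p = 0.106. The spermatogonial, Leydig, endothelial, myoid and macrophage lists did not pass, with camera adjusted p = 0.203, 0.534, 0.614, 0.809 and 0.686.

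In all, 623 genes differed between P25 and P18, 535 higher and 88 lower (85.9% higher). In coverage rescaled to the median gene 721 were higher and 248 lower (74.4% higher). The count was 149 with a mean of at least 5 FPKM, 190 with only the libraries of the 2 ages, 350 with a pseudocount of 5, 412 with the highest transfrag per gene and 294 in coverage with a 2-fold minimum. It was 330 without P18 replicate 2 (299 higher and 31 lower) and 403 without P25 replicate 2 (358 and 45), and 53 and 55 were lower without P25 replicate 1 and 3. Coverage called 975, of which 219 were lower, and 579 without P18 replicate 2 (107 lower) and 640 without P25 replicate 2 (124 lower). In coverage 130, 119 and 336 were lower without P18 replicate 1, P18 replicate 3 and P35 replicate 1. Short transfrags carried 98.4% of the FPKM of Crocc, whose call ended without any 1 of the 6 libraries compared, and 92.6% of that of Homer3. Their log2 changes were -7.12 and -3.91 in FPKM but 0.12 and 0.02 in coverage.

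Between P25 and P35, when elongated spermatids appear, spermatid genes rose further. Of the 25 spermatid genes at P35, 22 rose, 0 fell and 3 did not pass (24 rose and 0 fell adjusted over the list alone). The spermatid list was higher as a group (camera adjusted p = 7.7e-35, adjusted p = 0.105 with an estimated correlation). Prm1 rose from 8.17 ± 3.47 to 1787 ± 192 FPKM (log2 change 7.68 ± 0.42, adjusted p = 4.6e-08). Prm2, for the other protamine, rose from 3.90 ± 1.003 to 975 ± 144 FPKM (log2 change 7.65 ± 0.17, adjusted p = 8.7e-11). Tnp1 rose from 4.78 ± 2.15 to 1009 ± 167 FPKM (log2 change 7.50 ± 0.24, adjusted p = 7.1e-10). Smcp, for a sperm mitochondrial protein, rose from 4.18 ± 0.801 to 498 ± 65.1 FPKM (log2 change 6.59 ± 0.16, adjusted p = 1.2e-10). Of the spermatocyte genes at P35, 5 rose, 5 fell and 12 did not pass (5 rose and 7 fell adjusted over the list alone). In coverage 6 rose and 0 fell. The list did not pass as a group (camera adjusted p = 0.919). Ldhc rose from 60.04 ± 8.17 to 191 ± 61.6 FPKM (log2 change 1.61 ± 0.22, adjusted p = 2.5e-04). Of the spermatogonial genes at P35, 1 rose, 1 fell and 16 did not pass (the same adjusted over the list alone). The list did not pass as a group (camera adjusted p = 0.734).

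Of the Leydig genes at P35, 4 rose, 1 fell and 5 did not pass (7 rose and 2 fell adjusted over the list alone). The Leydig list was higher as a group (camera adjusted p = 0.0104, adjusted p = 0.152 with an estimated correlation). Insl3 rose from 1.54 ± 0.698 to 27.9 ± 3.13 FPKM (log2 change 3.54 ± 0.29, adjusted p = 2.2e-06). The steroidogenic enzyme gene Cyp17a1 rose from 0.272 ± 0.110 to 6.98 ± 1.31 FPKM (log2 change 2.64 ± 0.29, adjusted p = 3.2e-05). Of the myoid genes at P35, 2 rose, 1 fell and 7 did not pass (2 rose and 2 fell adjusted over the list alone). The myoid list did not pass as a group (camera adjusted p = 0.494). The smooth muscle actin gene Actg2 rose from 0.761 ± 0.0843 to 30.7 ± 6.52 FPKM (log2 change 4.15 ± 0.17, adjusted p = 4.7e-09). Its near-identical relative Acta2 fell from 16.4 ± 1.77 to 8.73 ± 1.22 FPKM (log2 change -0.85 ± 0.12, adjusted p = 4.1e-04), and both values are uncertain, since reads can be split between them. Of the macrophage genes at P35, 2 rose, 0 fell and 10 did not pass (2 rose and 0 fell adjusted over the list alone). The macrophage list did not pass as a group (camera adjusted p = 0.175, adjusted p = 0.403 with an estimated correlation), but passed in coverage (higher, adjusted p = 0.0132, adjusted p = 0.267 with an estimated correlation). Aif1 rose from 1.33 ± 0.435 to 43.2 ± 8.87 FPKM (log2 change 4.24 ± 0.67, adjusted p = 7.7e-04). Of the endothelial genes at P35, 1 rose, 1 fell and 9 did not pass (1 rose and 1 fell adjusted over the list alone). The endothelial list did not pass as a group (camera adjusted p = 0.404). Alas2, the only measured gene of the erythroid list, rose from 7.15 ± 4.73 to 83.2 ± 26.9 FPKM (log2 change 3.47 ± 0.40, adjusted p = 5.1e-05). The list's globin names were not matched, and the globin gene Beta-s was not in it. With Alas2 alone, the erythroid list test (camera adjusted p = 0.0427, adjusted p = 0.244 with an estimated correlation) describes no group. It did not pass without P35 replicate 1, 2 or 3 (adjusted p = 0.0577, 0.0652 and 0.0538).

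Of the immediate-early genes at P35, 0 rose, 8 fell and 11 did not pass (0 rose and 8 fell adjusted over the list alone). The immediate-early list was lower as a group (camera adjusted p = 0.00693, adjusted p = 0.511 with an estimated correlation). Egr1 fell from 77.1 ± 20.1 to 8.75 ± 3.53 FPKM (log2 change -3.03 ± 0.57, adjusted p = 0.00286). Fos fell from 87.6 ± 31.2 to 11.6 ± 5.85 FPKM (log2 change -2.85 ± 0.48, adjusted p = 0.00131). Among other genes, B2m, for the light chain of MHC class I, fell from 130.3 ± 44.8 to 18.9 ± 1.99 FPKM (log2 change -2.66 ± 0.26, adjusted p = 1.2e-05). Of the junction genes at P35, 0 rose, 5 fell and 23 did not pass (0 rose and 5 fell adjusted over the list alone). The junction list was lower as a group (camera adjusted p = 0.0274, adjusted p = 0.499 with an estimated correlation); the adjusted p was 0.0712 in coverage, 0.0579 without P25 replicate 1 and 0.0710 without P35 replicate 1. Of the core Sertoli genes at P35, 0 rose, 2 fell and 18 did not pass (0 rose and 0 fell adjusted over the list alone). The core Sertoli list did not pass as a group (camera adjusted p = 0.404). Of the mature Sertoli genes at P35, 0 rose, 2 fell and 14 did not pass (0 rose and 1 fell adjusted over the list alone). The mature Sertoli list did not pass as a group (camera adjusted p = 0.0653, adjusted p = 0.403 with an estimated correlation), but passed without both P5 library 3 and P10 library 1 (adjusted p = 0.0300, adjusted p = 0.291 with an estimated correlation) and without P5 replicate 3 or P25 replicate 3 singly, and not in coverage (adjusted p = 0.222). With an estimated correlation its lowest adjusted p without any 1 library was 0.330. Shbg fell from 213 ± 34.7 to 92.2 ± 7.03 FPKM (log2 change -1.19 ± 0.22, adjusted p = 0.00253). Col18a1, a basement membrane collagen gene, fell from 413 ± 42.1 to 148 ± 42.0 FPKM (log2 change -1.51 ± 0.35, adjusted p = 0.0111). Cdkn1a rose from 15.8 ± 5.33 to 41.2 ± 16.1 FPKM (log2 change 1.31 ± 0.26, adjusted p = 0.00441).

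In all, 3274 genes differed between P35 and P25, 1766 higher and 1508 lower (53.9% higher). The median gene changed by -0.17 on the log2 scale in FPKM and by -0.05 in coverage, and a decrease in FPKM smaller than that shift is not read as a fall. With gene sums rescaled to the median gene 2080 were higher and 834 lower (71.4% higher). With gene sums quantile-normalized again the majority turned, with 1765 higher and 2070 lower (46.0% higher). The majority also turned with a pseudocount of 0.1 (1546 and 1571), a mean of at least 5 FPKM (486 and 1141), exon-overlapping transfrags (1818 and 2400) and without short transfrags (1862 and 2493). The 2-fold minimum gave 1560 and 496, and 1163 and 131 in coverage. Coverage gave 2139 and 1040 (67.3% higher), and rescaled coverage 2209 and 941 (70.1% higher). The number lower moved with single libraries. In FPKM it was 2296 without P5 replicate 3 (1865 higher, so that the majority turned), 859 and 898 without P25 replicate 2 and 3, and 775 without P35 replicate 3. In coverage it was 594 without P25 replicate 3, 644 without P35 replicate 1 or 3, and 1857 without P35 replicate 2. Without P5 library 3 and P10 library 1 in the fit, 1939 were higher and 2920 lower. Sox9 was at 903 ± 24.9 and 472 ± 32.7 FPKM (log2 change -0.94 ± 0.52, adjusted p = 0.268). Clu was at 12815 ± 1614 and 5298 ± 1661 FPKM (log2 change -1.32 ± 1.64, adjusted p = 0.668). Its coverage was 6982 to 7902 and 5647 to 7988. The stem cell factor gene's call, Kitl P35 against P25 (-0.995 ± 0.30, adjusted p = 0.0402), ended without P5 replicate 1, P10 replicate 3, P18 replicate 1 or 3, any P25 library, or P35 replicate 1 or 3 (adjusted p up to 0.130 without P25 replicate 3). Kitl did not pass in coverage (adjusted p = 0.0998) or with rescaled gene sums (0.0831). Tmem147 had a log2 change of -6.52 in FPKM and 0.37 in coverage. For 1700067C01Rik, with 99.7% of its FPKM on short transfrags, the values were 9.06 and 0.96.

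Over the whole interval, P35 against P5, each of the 28 cell cycle genes fell and each of the 25 spermatid genes rose. The cell cycle list was lower as a group (camera adjusted p = 9.3e-15, adjusted p = 0.152 with an estimated correlation), with a median log2 change of -3.17. Adjusted over the list alone, 28 fell. Ube2c fell from 157 ± 70.8 to 1.46 ± 0.279 FPKM (log2 change -5.88 ± 0.34, adjusted p = 4.1e-08). Cdkn1a rose from 0.486 ± 0.0800 to 41.2 ± 16.1 FPKM (log2 change 4.76 ± 0.26, adjusted p = 2.3e-08). Cdkn2b, for another inhibitor, rose from 0.260 ± 0.0739 to 19.1 ± 6.97 FPKM (log2 change 3.95 ± 0.22, adjusted p = 2.9e-08). The spermatid list was higher as a group (camera adjusted p = 1.8e-17, adjusted p = 0.152 with an estimated correlation), with a median of 4.71, and 25 genes rose adjusted over the list alone. Prm2 and Smcp were listed at 0 in the 3 P5 libraries and at 975 ± 144 and 498 ± 65.1 FPKM at P35 (adjusted p = 8.0e-12 and 8.0e-12).

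Gata1 rose from 12.1 ± 2.21 to 132 ± 34.7 FPKM (log2 change 3.33 ± 0.19, adjusted p = 3.7e-08) over the whole interval. Drd4 rose from 3.55 ± 2.06 to 289 ± 38.5 FPKM (log2 change 6.08 ± 0.43, adjusted p = 2.2e-07). Cldn11 rose from 168 ± 74.4 to 1444 ± 213 FPKM (log2 change 3.18 ± 0.61, adjusted p = 8.3e-04). Spinlw1 rose from 4.97 ± 0.804 to 189.9 ± 30.7 FPKM (log2 change 4.996 ± 0.28, adjusted p = 2.5e-08). Amh fell from 745 ± 554 to 45.4 ± 6.05 FPKM (log2 change -3.42 ± 0.82, adjusted p = 0.00392). Gata4 fell from 277 ± 115 to 87.2 ± 34.3 FPKM (log2 change -1.64 ± 0.34, adjusted p = 0.00164). Dmrt1, a sex-determination gene, fell from 219 ± 93.97 to 69.7 ± 4.74 FPKM (log2 change -1.53 ± 0.35, adjusted p = 0.00308). Gdnf fell from 56.7 ± 11.4 to 4.34 ± 1.17 FPKM (log2 change -3.44 ± 0.21, adjusted p = 5.4e-08). Kitl fell from 88.9 ± 19.8 to 20.96 ± 8.40 FPKM (log2 change -2.08 ± 0.30, adjusted p = 8.7e-05). Of the core Sertoli genes over the whole interval, 5 rose, 4 fell and 11 did not pass (5 rose and 4 fell adjusted over the list alone). The core Sertoli list did not pass as a group (camera adjusted p = 0.946), with a median of 0.25 and a mean of 0.47 on the log2 scale while the test pointed lower. Of the immature genes over the whole interval, 2 rose, 6 fell and 6 did not pass (2 rose and 6 fell adjusted over the list alone). The immature Sertoli list did not pass as a group (camera adjusted p = 0.0829, adjusted p = 0.727 with an estimated correlation), but passed in coverage (lower, adjusted p = 0.0281, adjusted p = 0.470 with an estimated correlation), without both P5 library 3 and P10 library 1 (adjusted p = 0.0356, adjusted p = 0.389 with an estimated correlation) and without P5 replicate 3. With an estimated correlation its lowest adjusted p without any 1 library was 0.325. Of the mature genes over the whole interval, 8 rose, 3 fell and 5 did not pass (8 rose and 3 fell adjusted over the list alone). The mature Sertoli list did not pass as a group (camera adjusted p = 0.218).

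Sox9 was at 704 ± 363 and 472 ± 32.7 FPKM (log2 change -0.40 ± 0.52, adjusted p = 0.546), and in coverage it fell (log2 change -1.02 ± 0.25, adjusted p = 0.00175). Wt1 was at 99.8 ± 22.5 and 74.2 ± 6.17 FPKM (log2 change -0.40 ± 0.17, adjusted p = 0.0631), and in coverage it fell (log2 change -0.40 ± 0.14, adjusted p = 0.0210). Of the growth factor genes over the whole interval, 0 rose, 11 fell and 8 did not pass (0 rose and 11 fell adjusted over the list alone). The growth factor list was lower as a group (camera adjusted p = 5.8e-04, adjusted p = 0.390 with an estimated correlation). Of the imprinted genes over the whole interval, 3 rose, 10 fell and 3 did not pass (3 rose and 10 fell adjusted over the list alone). The imprinted list was lower as a group (camera adjusted p = 0.00473, adjusted p = 0.403 with an estimated correlation). H19 fell from 64.0 ± 20.2 to 0.0975 ± 0.127 FPKM (log2 change -5.85 ± 0.26, adjusted p = 4.3e-09). Of the immediate-early genes over the whole interval, 0 rose, 11 fell and 8 did not pass (0 rose and 12 fell adjusted over the list alone). The immediate-early list was lower as a group (camera adjusted p = 3.6e-04, adjusted p = 0.403 with an estimated correlation). Fos fell from 306 ± 171 to 11.6 ± 5.85 FPKM (log2 change -4.48 ± 0.48, adjusted p = 8.1e-06). Mmp2 fell from 170.4 ± 97.8 to 0.0444 ± 0.0681 FPKM (log2 change -7.16 ± 0.51, adjusted p = 2.4e-07). Timp2 rose from 5.01 ± 0.559 to 326 ± 30.7 FPKM (log2 change 5.77 ± 0.27, adjusted p = 5.8e-09). Of the spermatocyte genes over the whole interval, 14 rose, 1 fell and 7 did not pass (14 rose and 1 fell adjusted over the list alone). The spermatocyte list was higher as a group (camera adjusted p = 9.7e-04, adjusted p = 0.445 with an estimated correlation). The spermatogonial, Leydig, endothelial, myoid and macrophage lists did not pass, with camera adjusted p = 0.915, 0.525, 0.0669, 0.593 and 0.262. In coverage the endothelial list passed, lower (adjusted p = 0.0155, adjusted p = 0.448 with an estimated correlation), and the macrophage list, higher (adjusted p = 0.0286, adjusted p = 0.308 with an estimated correlation). The endothelial list also passed without P10 replicate 1 or P35 replicate 1, but not with an estimated correlation without any 1 library (lowest adjusted p = 0.467). Sox18, of the endothelial list, fell from 41.5 ± 10.05 to 0.183 ± 0.108 FPKM (log2 change -5.14 ± 0.20, adjusted p = 1.5e-09).

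In all, 10746 genes differed between P35 and P5, 5678 higher and 5068 lower (52.8% higher). With gene sums quantile-normalized again 5429 were higher and 5591 lower (49.3% higher), and without P5 replicate 3, 5194 and 5490. Without P5 library 3 and P10 library 1 they were 5455 and 5815, with a mean of at least 5 FPKM 2909 and 3175, and in coverage with a 2-fold minimum 3218 and 2620. In coverage 5743 were higher and 5635 lower, and without P35 replicate 2, 5572 and 5736. Across the 5 ages 11706 genes varied (limma F test), 6443 with a mean of at least 5 FPKM and 7022 in coverage with a 2-fold minimum. Of 125 list tests in FPKM, 36 passed with camera's preset correlation, 1 of them the erythroid list of 1 gene. With an estimated correlation 0 passed, 16 had an unadjusted p under 0.05, and fry, a test of whether a list's genes move one way on balance, passed 63. In coverage 37 list tests passed, and with an estimated correlation 2 did, the cell cycle list in P10 against P5 (adjusted p = 0.0147) and in P18 against P10 (0.0460). The log2 changes of 15100 genes measured in both readouts correlated across genes at 0.61 (P25 against P18) to 0.84 (P35 against P5), with 0.62 for P10 against P5. Of the genes called in both readouts, 2157, 2786, 418, 1680 and 7636 in the order of the comparisons above, 8, 17, 2, 4 and 118 had opposite directions.

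**Figure D2:**
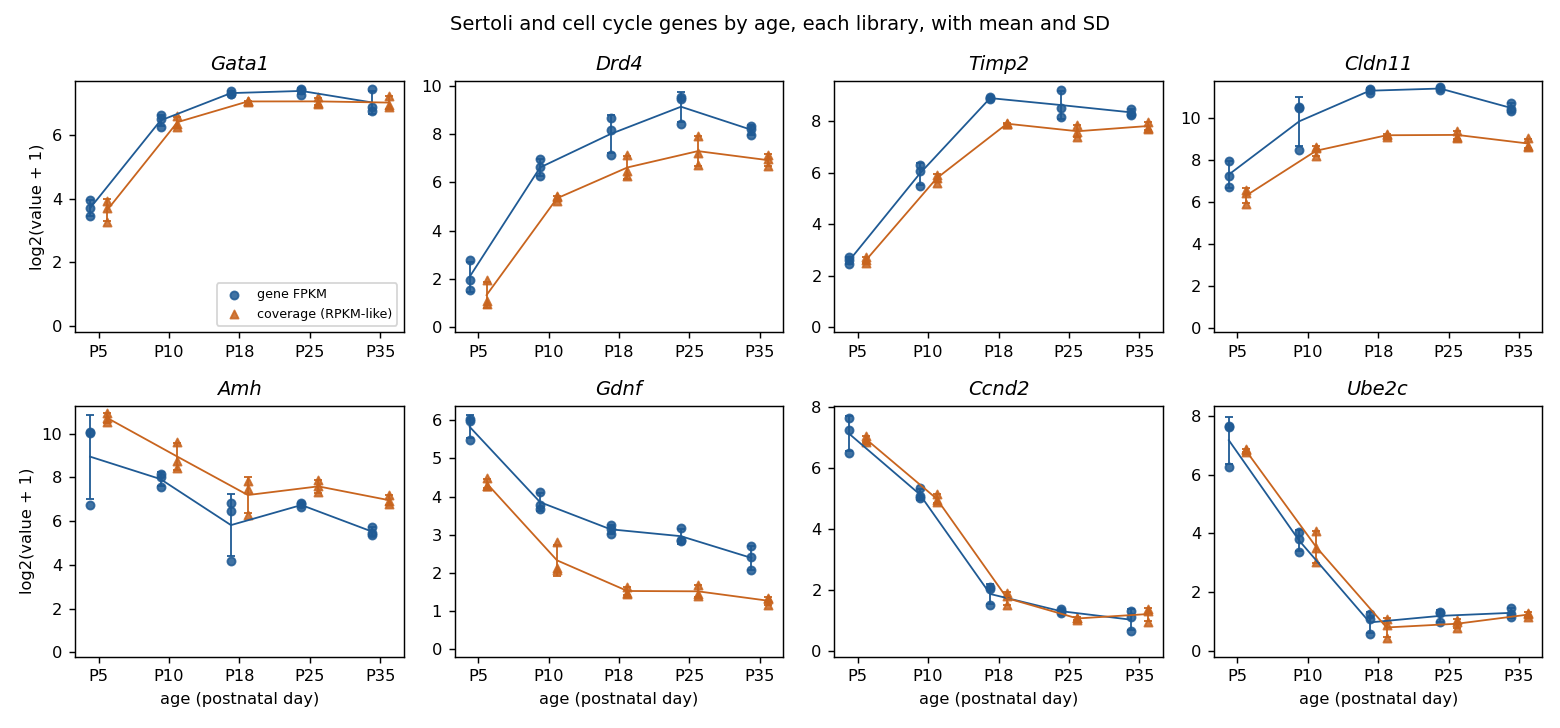
Each panel plots 1 gene (Gata1, Drd4, Timp2, Cldn11, Amh, Gdnf, Ccnd2 and Ube2c) by age, with ages evenly spaced on the horizontal axis and log2(value + 1) on the vertical axis, in FPKM and in read coverage; points are libraries, lines join means and bars are SD (n = 3). Gata1, Drd4, Timp2 and Cldn11 lie higher at P35 than at P5, and Amh, Gdnf, Ccnd2 and Ube2c lie lower.

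**Figure D3:**
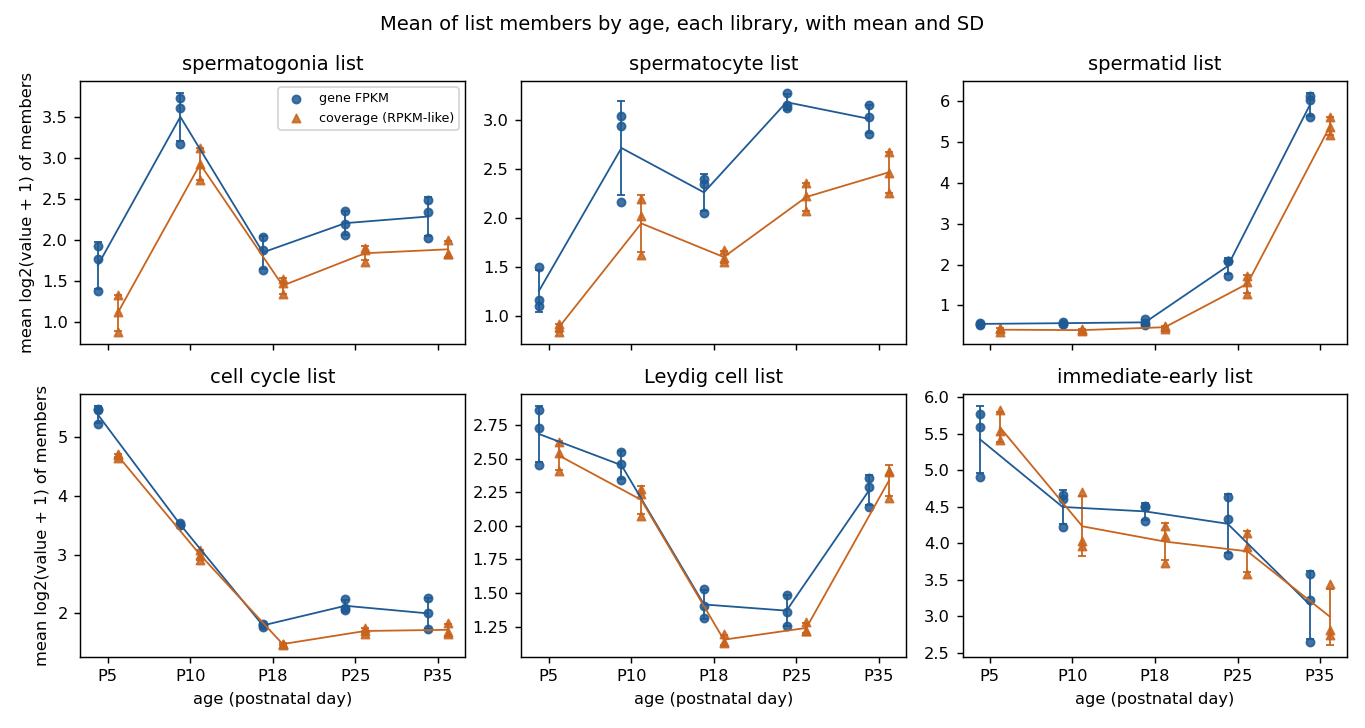
Each panel plots the mean log2(value + 1) of the measured members of 1 list in each library by age, with ages evenly spaced, in FPKM and in read coverage, with the mean and SD of 3 libraries. The spermatid list is highest at P35, the spermatogonial list at P10, and the cell cycle list at P5.

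Loci outside the annotation were tested apart. Of 1019 assembled intergenic loci, 354 varied over the ages (limma F test, adjusted within these loci), against 22 of 222 with a mean of at least 5 FPKM and 108 of 135 in coverage. Of these, 179 were highest at P35, 48 of them with more than 1 exon. The loci with the smallest p were mostly single-exon transfrags of under 200 bases and are uncertain. A locus on chromosome 15 (100897020 to 100897132 in mm9) had 208 ± 103 FPKM at P10 and was listed at 0 at the other ages (adjusted p = 3.3e-07). A longer locus on chromosome 19 (56795792 to 56796472) reached 25.4 ± 8.77 FPKM at P25 and 0.523 ± 0.0517 at P35 (adjusted p = 6.9e-07), while its mean coverage was 0.333 and 0.353.

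In the mouse build mm9, the transfrags carrying these gene symbols, exons and introns included, spanned the following intervals. Sox9 lay on chromosome 11, 112642202 to 112649042, Gata1 on chromosome X, 7536382 to 7555043, and Drd4 on chromosome 7, 148477863 to 148482776. Cldn11 lay on chromosome 3, 31047899 to 31065573, Amh on chromosome 10, 80268528 to 80270735, and Gdnf on chromosome 15, 7758935 to 7788535. Ccnd2 lay on chromosome 6, 127075179 to 127104778, Ube2c on chromosome 2, 164595351 to 164604125, and Timp2 on chromosome 11, 118162374 to 118216826. Prm1 lay on chromosome 16, 10795961 to 10797805, Tnp1 on chromosome 1, 73061646 to 73062908, and Insl3 on chromosome 8, 74213053 to 74214468.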

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

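Alternatives on exon-overlapping or longer transfrags and without both P5 library 3 and P10 library 1 were chosen after the data were seen. So were coverage rescaled, with a 2-fold minimum or of loci, and list tests on coverage, without both libraries or each, with either correlation. Of the 289 gene comparisons named, 230 were called and 207 kept their call without each library in turn. Without some library 23 lost it and 10 gained one. No call of a named gene reversed direction under the pseudocounts, filters, rescalings, eBayes settings, 2-fold minimum, block or left-out libraries. Turns of direction in genes not called in either fit were not counted. In coverage 238 of 281 comparisons kept their side of the threshold, called or not, and where called also their direction. Another 9 lost and 24 gained a call in the same direction, and 10 reversed. Calls that held were preferred in naming, so these counts do not measure robustness. Depth's limit on low transcripts was not tested.

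Leaving out each library in turn gave 2605 to 3771 genes for P10 against P5, 3032 to 4915 for P18 against P10 and 330 to 690 for P25 against P18. It gave 2319 to 4161 for P35 against P25, 9565 to 11108 for P35 against P5 and 10563 to 11974 across the ages. For P25 against P18 the lowest came without P18 replicate 2, and 403 without P25 replicate 2. List tests past the threshold numbered 34 to 42, loci 324 to 397, and 35 to 44 of the 50 genes of largest change were chosen again.

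A minimum mean of 5 FPKM tested 12160 genes and called 2120, 2258, 149, 1627, 6084 and 6443 (the 5 comparisons in order, then across the ages), and 22 of 222 loci; fewer genes and loci were tested. A pseudocount of 5 gave 350 for P25 against P18. The highest transfrag per gene gave 2565 for P18 against P10 and 412 for P25 against P18. Only the libraries of the 2 ages gave 1602 for P10 against P5 and 190 for P25 against P18, with fewer samples to estimate the spread. The 2-fold minimum gave 2056 for P35 against P25. Coverage gave 975 for P25 against P18 (579 to 1265 without each library in turn), 969 when rescaled, and 108 of 135 loci. Coverage with a 2-fold minimum gave 1421, 1598, 294, 1294, 5838 and 7022, a stricter criterion by construction. Of the 50 genes of largest change, 28 were chosen again with a pseudocount of 0.1, 11 with the highest transfrag, 7 in coverage, 10 without transfrags of 200 bases or fewer and 32 without P5 library 3 and P10 library 1. Except where a reason is given, the cause was not tested.

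Against 36 list tests with camera's preset correlation, 0 passed with an estimated correlation (16 at an unadjusted p under 0.05), 63 with fry to the same side and 100 with fry to either side. Of the 36, 23 held under each alternative but the estimated correlation, 7 were lost without 1 library and 7 in coverage, while of the others 8 passed in coverage (37 in all), 6 without both P5 library 3 and P10 library 1 (42 in all) and 11 without some library. The 8 include the cholesterol list in P10 against P5 (adjusted p = 0.0286, adjusted p = 0.448 with an estimated correlation). The 6 include the hormone receptor and phagocytosis lists in P35 against P25 (0.0496 and 0.0229, adjusted p = 0.250 and 0.429 with an estimated correlation). With an estimated correlation 2 tests passed in coverage, each of the cell cycle list, and 0 without both libraries. Without each library in turn, 2 passed in some fit, the spermatid list in P25 against P18 and in P35 against P25 (0.0204 each, without P35 replicate 2). For each of the 36 the highest adjusted p over its alternatives came with an estimated correlation. The myoid list in P35 against P5 turned direction in fry (adjusted p = 0.0362). Log2 changes of single genes also turned. For P10 against P5, Fshr was at -0.6051 in coverage, -0.6565 over exon-overlapping transfrags and -0.5166 without short ones, each past the threshold. Parp16 was at -0.0214 and Fance at -0.0575 in coverage. BC107364 was at -0.0651 over exon-overlapping transfrags and without short ones. Ccnyl1 was at 0.0052 in coverage, 0.1213 over exon-overlapping transfrags and 0.1079 without short ones. For P18 against P10, Fshr was at 0.4400 in coverage and 0.5925 over exon-overlapping transfrags, both past the threshold, and Parp16 at 0.3730 in coverage. For P25 against P18, 2410187C16Rik was at -0.3254 in coverage and -0.7970 without short transfrags, and Crocc at 0.1190 and 0.3589. In coverage, Homer3 was at 0.0208, and Tmem147 at 0.3707 for P35 against P25. The cause was not tested.

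With the replicate number as a replicate block, 3197, 3856, 494, 2971 and 10594 genes were called in the 5 comparisons and 11288 across the ages, with 35 list tests and 328 loci. With it 3 named gene calls were lost, and the junction list in P25 against P18 (adjusted p = 0.0552) and the erythroid list in P35 against P25 (0.0560) did not pass, while the cholesterol list in P10 against P5 did (0.0431). The shared numbers do not pair the libraries, since the correlations of same-numbered deviations ran from -0.0988 to 0.0484 in FPKM and from -0.393 to 0.410 in coverage (30 pairs). Of the 15 libraries, 5 in FPKM and 7 in coverage were closest to their own number.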

Other observations

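The tests weighing the spermatid transcripts and the pair of libraries standing apart were chosen only after those results were seen. Of 24 oxidative phosphorylation genes, limma passed 0 in FPKM between P18 and P25 (0 at an unadjusted p under 0.05, and 0 higher and 0 lower in coverage). The oxidative phosphorylation list in P25 against P18 did not pass as a group (camera adjusted p = 0.103, adjusted p = 0.823 with an estimated correlation), but passed in coverage (higher, adjusted p = 0.00804, adjusted p = 0.470 with an estimated correlation), without both P5 library 3 and P10 library 1 (adjusted p = 4.8e-04, adjusted p = 0.389 with an estimated correlation) and without P5 replicate 3. With an estimated correlation its lowest adjusted p without any 1 library was 0.703. From P5 to P35, 2 rose, 1 fell and 21 did not pass (2 rose and 1 fell adjusted over the list alone). The oxidative phosphorylation list did not pass as a group (camera adjusted p = 0.534). Ndufa1, for a subunit of respiratory complex I, rose from 11.3 ± 3.08 to 42.9 ± 7.80 FPKM (log2 change 1.86 ± 0.29, adjusted p = 1.9e-04). Of 20 glycolysis and lactate genes from P10 to P18, 5 rose, 3 fell and 12 did not pass (6 rose and 5 fell adjusted over the list alone). The glycolysis list did not pass as a group (camera adjusted p = 0.555). Of the glycolysis genes from P25 to P35, 3 rose, 3 fell and 14 did not pass (5 rose and 4 fell adjusted over the list alone). The glycolysis list did not pass as a group (camera adjusted p = 0.788), with a median of -0.37 and a mean of 0.32 on the log2 scale while the test pointed higher. Gpi1, for glucose phosphate isomerase, rose from 31.8 ± 3.11 to 94.8 ± 31.2 FPKM (log2 change 1.499 ± 0.25, adjusted p = 0.00120). The glucose transporter gene Slc2a3 had a log2 change of 4.41 in FPKM and 0.44 in coverage, with 86.9% of its FPKM on short transfrags. Of the glycolysis genes from P5 to P35, 8 rose, 4 fell and 8 did not pass (8 rose and 4 fell adjusted over the list alone). The glycolysis list did not pass as a group (camera adjusted p = 0.284). Slc16a1 rose from 12.2 ± 2.75 to 42.4 ± 4.72 FPKM (log2 change 1.73 ± 0.26, adjusted p = 1.4e-04). Ldhb, for the lactate dehydrogenase B subunit, rose from 257 ± 152 to 1109.5 ± 210.4 FPKM (log2 change 2.35 ± 0.64, adjusted p = 0.00836).

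Of 19 lipid handling genes from P10 to P18, 5 rose, 1 fell and 13 did not pass (8 rose and 1 fell adjusted over the list alone). The lipid handling list was higher as a group (camera adjusted p = 0.0104, adjusted p = 0.403 with an estimated correlation), and in coverage adjusted p = 0.105. Of the lipid handling genes from P5 to P35, 11 rose, 3 fell and 5 did not pass (11 rose and 3 fell adjusted over the list alone). The lipid handling list did not pass as a group (camera adjusted p = 0.223). Acsl1, for an enzyme that activates fatty acids, rose from 3.14 ± 0.517 to 29.1 ± 1.79 FPKM (log2 change 2.87 ± 0.16, adjusted p = 3.2e-08). Lpl fell from 55.5 ± 19.4 to 0.142 ± 0.228 FPKM (log2 change -5.58 ± 0.36, adjusted p = 9.5e-08). Of 21 cholesterol synthesis genes, limma passed 0 from P18 to P25 (8 at an unadjusted p under 0.05, and 2 higher and 0 lower in coverage). The cholesterol list was higher as a group (camera adjusted p = 0.0200, adjusted p = 0.565 with an estimated correlation); the adjusted p was 0.0796 in coverage, and 0.0523, 0.0837 and 0.0898 without P18 replicate 3, P25 replicate 1 and P25 replicate 2, and fry adjusted p = 0.0569. Of the cholesterol genes from P25 to P35, 0 rose, 4 fell and 17 did not pass (1 rose and 8 fell adjusted over the list alone). The cholesterol list was lower as a group (camera adjusted p = 0.0143, adjusted p = 0.529 with an estimated correlation), and in coverage adjusted p = 0.0664. Of the cholesterol genes from P5 to P35, 4 rose, 6 fell and 11 did not pass (4 rose and 6 fell adjusted over the list alone). The cholesterol list did not pass as a group (camera adjusted p = 0.741), with a median of 0.24 and a mean of -0.01 on the log2 scale while the test pointed lower. Ebp, for a late enzyme of the pathway, rose from 35.1 ± 5.73 to 92.9 ± 21.3 FPKM (log2 change 1.37 ± 0.18, adjusted p = 3.6e-05). Srebf2, for its transcriptional activator, fell from 45.3 ± 8.74 to 17.7 ± 3.89 FPKM (log2 change -1.31 ± 0.18, adjusted p = 7.8e-05).

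Of 17 hormone receptor genes from P5 to P35, 3 rose, 11 fell and 3 did not pass (3 rose and 11 fell adjusted over the list alone). The hormone receptor list was lower as a group (camera adjusted p = 0.0211, adjusted p = 0.228 with an estimated correlation), and in coverage adjusted p = 0.105. Thra, for a thyroid hormone receptor, fell from 247 ± 74.2 to 25.6 ± 3.57 FPKM (log2 change -3.18 ± 0.23, adjusted p = 2.1e-07). Of the basement membrane genes from P5 to P35, 5 rose, 14 fell and 5 did not pass (5 rose and 14 fell adjusted over the list alone). The basement membrane list was lower as a group (camera adjusted p = 0.0399, adjusted p = 0.511 with an estimated correlation); the adjusted p was 0.0684 in coverage, 0.0530 with a pseudocount of 0.1 and 0.0571 without P5 replicate 2. Of 28 junction genes, limma passed 0 from P18 to P25 (4 at an unadjusted p under 0.05, and 0 higher and 1 lower in coverage). The junction list was lower as a group (camera adjusted p = 0.0390, adjusted p = 0.511 with an estimated correlation); the adjusted p was 0.0776, 0.0574 and 0.0713 without P18 replicate 1, P25 replicate 2 and P25 replicate 3, and fry adjusted p = 0.322 to the same side and 0.104 to either side. Of the phagocytosis genes from P5 to P35, 10 rose, 4 fell and 8 did not pass (10 rose and 4 fell adjusted over the list alone). The phagocytosis list did not pass as a group (camera adjusted p = 0.254). Pros1 rose from 3.76 ± 0.748 to 68.9 ± 6.98 FPKM (log2 change 3.88 ± 0.27, adjusted p = 2.0e-07). Of the retinoic acid genes from P5 to P35, 5 rose, 7 fell and 8 did not pass (5 rose and 7 fell adjusted over the list alone). The retinoic acid list did not pass as a group (camera adjusted p = 0.577), with a median of -0.22 and a mean of 0.06 on the log2 scale while the test pointed lower. Cst12, a cystatin gene, was at 19.3 ± 4.74 and 30.3 ± 9.72 FPKM (log2 change 0.59 ± 0.34, adjusted p = 0.169), and in coverage it rose (log2 change 2.22 ± 0.25, adjusted p = 1.2e-06).

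Germ cell transcripts were higher at P35 (Prm1 1787 ± 192, Prm2 975 ± 144, Tnp1 1009 ± 167 FPKM) than at P25. The tables argue against normalization by the authors as the whole source, since coverage, which does not use it, gave the spermatid list a median log2 change of 3.85 (bootstrap interval 1.75 to 5.42). A lower share of Sertoli cells stays open, since the test required each other type to rise alike, and germ cells alone could lower it. The medians of the Leydig, myoid, macrophage and endothelial lists were above 0, which met the criterion written first. By a bound added after these values were seen, 3 of 4 intervals lay below the spermatid list's. Their upper ends were 1.25, 1.52 and 0.300 (myoid, macrophage, endothelial), while Leydig (-0.50 to 2.36) overlapped. Carry-over of germ cells or of their RNA stays open as a hypothesis. The value at hand, 100% of the 25 measured spermatid genes higher in coverage, only restates the rise. Of them, 4 were already at 1 FPKM or more at P5. A change with age in the Sertoli cells themselves or in what they take up was not tested. A sort on the fluorescent protein, if used, would select for cells with Sox9, but its purity is not given in the sources used here.

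P5 library 3 and P10 library 1 stood apart in FPKM, where their mean correlation with replicates was 0.0743 below that of the other libraries. RNA degradation would lower the 5' share of coverage. In P10 library 1 it was 58.5%, 20.3 points above the lower of its replicates (38.2 and 43.7%). In P5 library 3 it was 57.7%, against 52.0 and 57.2% (medians of 6502 genes). The authors' processing of FPKM values stays open for both. In coverage P5 library 3 correlated with its replicates at 0.990, above 11 of the other 13. Its reads lay on 82.9 megabases of genome, against 97.8 and 101, despite the most sequence. P10 library 1 covered 70.6, against 80.2 and 97.7. In coverage it correlated at 0.973, with 0 of the other 13 lower (next 0.974), and single genes differed, as Sox9 (265 against 126 and 138). No biological explanation was tested, and without both libraries the counts were 3973, 4117, 602, 4859 and 11270 in the 5 comparisons and 12419 across the ages.

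Regrouping the libraries was planned beforehand. In each comparison the 6 libraries make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes. The real values and the highest of the other splits were 3454 and 18 for P10 against P5, 4124 and 4 for P18 against P10, 623 and 2 for P25 against P18, 3274 and 23 for P35 against P25, and 10746 and 7 for P35 against P5. Across the ages 1 of 100 splits, the real one, gave 11706 genes and the highest other 5098, so that chance was excluded at 0.05. The same held for intergenic loci, at 1 of 100 (354, highest other 112). For the list tests 9 of 100 splits gave as many as the real 36, with a highest of 44, so that chance was not excluded for their number.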
